A study of Mus musculus with 2 samples.

How the data were processed

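The data were 2 droplet 5' gene expression libraries of sorted splenic CD8 T cells, sequenced on a NovaSeq S4, with 1 library of CD45.2+ old recipient cells and 1 of CD45.1+ young donor cells. Raw UMI counts per gene and barcode were used as deposited, without normalization by the submitters. Per the submitters' processing notes, Cell Ranger and Seurat were used with the mm10 build to make these counts, and per the file headers the software version behind the counts was 3.0.2. The annotation release and the rules for calling cells were not stated. The matched receptor libraries were not used here, and reads were not analysed here. The labels did not say whether both libraries came from the same mouse or from pools.

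Genes were placed with GENCODE M21 (GRCm38), which held 30934 of the 31053 features (99.6%), and 71 features sharing a symbol were summed to 31017 symbols. The recipient library had 6174 barcodes and 41504941 UMIs, and the donor library 8588 barcodes and 65006187 UMIs. Barcodes with fewer than 500 genes or more than 10% mitochondrial UMIs were left out, 555 in the recipient and 587 in the donor. Doublets were scored in each library against 2 simulated doublets per cell over 1500 genes, and the highest scores were removed at 0.8% per 1000 barcodes, 278 (4.95%) in the recipient and 550 (6.87%) in the donor. Kept cells held 38094125 and 58255304 UMIs, so 1 UMI was 0.0263 and 0.0172 CPM, and the tenth percentile of UMIs per cell was 3581 and 4069. Median mitochondrial shares were 2.87% and 3.02%, and ribosomal protein genes took 40.3% and 41.4% of UMIs.

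Counts were scaled to 10000 per cell, logged, and reduced over 2000 variable genes to 30 components, with values capped at 10. Receptor and immunoglobulin segments and ribosomal, mitochondrial and sex-linked genes were not used for this. Both libraries were clustered together with 15 neighbours and Leiden resolution 1, which gave 18 clusters. A cluster was named when the mean log2 of a class's markers was at least 0.2, at least 3 markers were up by 0.5 or more, and its leading genes pointed to no other class more often. Leading genes were the top 10 found in at least 10% of its cells, with 5 CPM added in the folds. The markers of 16 classes were set before the data were examined, as were the groups, the comparisons, the gene lists, the rule for naming genes and 15 other settings. The naming thresholds were set after the data were seen. This gave 8 named classes and 5 unnamed clusters, and 5 classes with at least 100 cells in both libraries were compared. The rebuilt names are not those of the study, and a difference from it may come from them. A cluster made mostly of 1 library may be a feature of that library.

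UMIs were summed over cells per library and divided by the total of the same cells. With 1 library per group there was no test. Intervals of CPM are exact Poisson and those of shares exact binomial, and ratio intervals are exact for 2 Poisson sums. A ratio against 0 UMIs is given as the least fold at a limit of 3 counts. Genes named over all cells were the 12 highest and 12 lowest with at least 200 UMIs over both libraries and 50 CPM in one, without receptor segments, ribosomal, mitochondrial and unnamed gene models. Within classes the 6 highest and 6 lowest with at least 100 UMIs were named, and 15 genes were always named. The values of 2 measured genes are not reported here. The 30 gene lists were 20 for comparison, 9 for other cell types and 1 of sex-linked genes. List medians used members with at least 20 UMIs, with intervals from 400 Poisson redraws and percentiles among 10000 random lists from 20 expression bins, and examples had at least 100 UMIs. For shares of cells with a UMI, each cell was thinned to 3500 UMIs, and shallower cells were left out, 9.16% of recipient and 6.21% of donor cells. Each cell's leading Trbv segment was found in 97.3% of recipient and 96.6% of donor cells, and diversity was averaged over 1000 draws of equal numbers of cells.

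The 15 other settings were at least 1000 genes, at most 5% mitochondrial UMIs, no doublets removed, resolutions 0.6 and 1.5, 1000 variable genes, genes centred within each library, and each library clustered alone. The others were TMM scaling, totals without large gene families, list members with at least 1 or 100 UMIs, thinning to 1000 UMIs, no thinning, and at least 3 UMIs of the leading Trbv segment. Another 3 settings were chosen after the data were seen, namely leaving out the 3 most common Trbv segments of either library in a class, using the larger age-associated-like cluster alone, and looser naming of clusters. The procedure was tested on simulated data with 200 changed genes. Counts were drawn from the Poisson model that the intervals assume, so coverage near 95% was built in. Spread between cells, clones or mice was not simulated. Intervals of unchanged genes held 0 for 95.1% over all cells and 95.9% in age-associated-like cells, and changed genes fell on the right side for 86% and 60% at 1.25-fold and for 98% and 88% at 1.5-fold. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and in R 4.3.3 with edgeR 4.0.16.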

Results

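Splenic CD8 T cells of C57BL/6J mice were compared within an aged host. Total CD8 T cells of CD45.1 donors aged 3 months were transferred into CD45.2 recipients aged 24 months, and both populations were sorted from spleen 1 month later as CD45.1+ (young donor) or CD45.2+ (old recipient) CD3e+CD8a+ cells. Each population gave 1 droplet 5' gene expression library, so library and group cannot be told apart, no difference was tested, and every interval covers counting error only. After filtering, 5341 recipient cells (86.5% of barcodes) and 7451 donor cells (86.8%) were kept, with medians of 6957 and 7811 UMIs and of 1922 and 2050 genes per cell. Values are UMIs summed over cells and scaled to the total of the same cells (CPM), and ratios are log2 of recipient over donor with 95% intervals. Genes were placed on mm10 (GRCm38).

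Across all kept cells, and among genes with at least 50 CPM in one library, the granzyme gene Gzma (ENSMUSG00000023132, chromosome 13, 113093825 to 113100981) had the highest ratio, at 52.2 CPM (49.9 to 54.5) in the old recipient and 10.6 (9.81 to 11.5) in the young donor. This was 4.91-fold, a log2 ratio of 2.30 [2.16, 2.43]. Few cells carried it, since 1613 of the 1987 recipient UMIs lay in 188 effector-memory-like cells and 988 of them in 93 cells with Trbv29. Igfbp4 (chromosome 11, 99041244 to 99054392), which encodes an insulin-like growth factor binding protein, came next among these genes at 335 and 137 CPM, a ratio of 1.29 [1.2499, 1.33]. The antiproliferative gene Btg2 (chromosome 1, 134075170 to 134079120) stood at 123 and 58.4 CPM, a ratio of 1.08 [1.01, 1.14]. Gzmk (ENSMUSG00000042385, chromosome 13, 113171608 to 113225908), a granzyme gene close to Gzma, was 1.69-fold higher in the recipient, at 189 CPM (185 to 194) against 112 (109 to 115), with a log2 ratio of 0.76 [0.71, 0.80]. It led the larger age-associated-like cluster (17.4% and 12.7% of cells), so its ratio also carries that share. Rgcc (1.04 [0.97, 1.12]), Hist1h2ap (0.93 [0.88, 0.98]), Ccl4 (0.81 [0.75, 0.88]), Klrk1 (0.80 [0.71, 0.89]), which encodes NKG2D, and Itga4 (0.69 [0.63, 0.74]) were higher in the recipient too, as were Ptpn7 (0.80), Sp140 (0.74) and S100a4 (0.72). Igfbp4 and Rgcc were among the genes leading naive-like cluster 0 (25.8% and 8.63% of cells), so their ratios also carry its share.

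Among the same genes, the lowest ratio belonged to Ctse (chromosome 1, 131638306 to 131675505), which encodes the aspartic protease cathepsin E. It had 18.3 CPM (16.9 to 19.7) in the recipient and 82.2 (79.9 to 84.5) in the donor, a log2 ratio of -2.17 [-2.29, -2.05]. Fcgrt (chromosome 7, 45092990 to 45103851), the gene of the neonatal Fc receptor, had 29.7 and 101 CPM, a ratio of -1.76 [-1.85, -1.67]. The granzyme gene Gzmm (chromosome 10, 79689020 to 79695261) had 37.4 and 101 CPM, a ratio of -1.43 [-1.52, -1.35]. Ly6c2 (chromosome 15, 75108158 to 75111970) had 789.5 and 1420.1 CPM, a ratio of -0.85 [-0.87, -0.83]. Donor cells also had more Ifitm10 (-0.82), Samd3 (-0.81), Tbx21 (-0.69), which encodes T-bet, Gramd3 (-0.63), Il18r1 (-0.63), Ms4a4c (-0.63), Plek (-0.61) and Il2rb (-0.58 [-0.62, -0.54]), which encodes CD122.

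Among the 15 genes chosen for naming before the data were examined, Klrg1 (1.26 [1.09, 1.44]), Lag3 (1.21 [1.08, 1.35], chromosome 6, 124904361 to 124911705) and Gzmb (1.13 [1.01, 1.26]) were more than 2-fold higher in recipient cells. Pdcd1 (chromosome 1, 94038305 to 94052553), the gene of PD-1, had 17.1 CPM (15.9 to 18.5) and 10.2 (9.41 to 11.1), a ratio of 0.75 [0.58, 0.91]. Ifng (0.50 [0.33, 0.67]), Tox (0.48 [0.40, 0.56], chromosome 4, 6686353 to 6991557), Lef1 (0.33 [0.29, 0.37]), Ccr7 (0.28 [0.25, 0.32]) and Tcf7 (0.10 [0.06, 0.14]) were higher by less. Eomes (-0.18 [-0.25, -0.12]) and Cd44 (-0.49 [-0.59, -0.40]) were lower in the recipient. Ccl5 was nearly the same at 7837 and 7868 CPM.

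**Figure D1:**
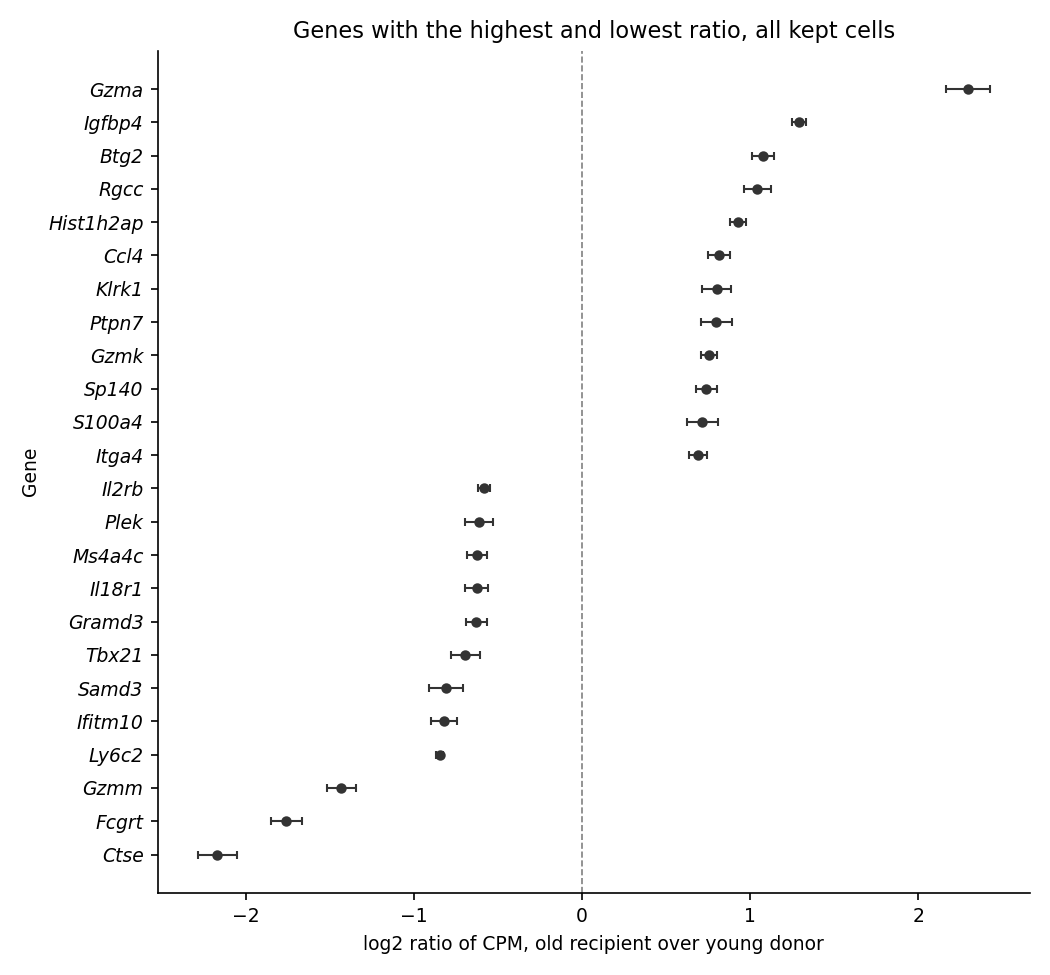
Log2 ratios of CPM, old recipient over young donor, of the 12 genes with the highest and the 12 with the lowest ratio over all kept cells. Bars are exact 95% intervals for counting error in 1 library per group.

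Over all cells, the lists of inhibitory receptors, effector memory genes and genes of Gzmk-expressing age-associated cells had positive medians. Their percentiles describe these 2 libraries beside 10000 random lists matched for expression. Of 10 inhibitory receptor genes, 7 were higher in the recipient, 1 was lower and 2 had intervals holding 0, with a median of 0.72 [0.61, 0.82] (percentile 100) and with Cd200 (1.94), Lag3 and Tigit (0.72) among the higher. Cd200 and Ctla4 were among the genes leading unnamed cluster 9 (4.47% and 1.80% of cells), so their ratios also carry its share. Of 14 effector memory genes, 9 were higher and 5 lower, with a median of 0.63 [0.50, 0.72] (percentile 100), and Cx3cr1 at 1.09 [0.91, 1.26]. Gzma, Gzmb, Klrg1 and Cx3cr1 were among the genes leading the effector-memory-like cluster (3.52% and 1.62% of cells), so their ratios also carry its share. Of 14 genes of the age-associated program, 11 were higher and 1 was lower, with a median of 0.50 [0.42, 0.58] (percentile 100). Pdcd1, Lag3, Tigit, Ctla4 and Cd160 belonged to both this list and that of inhibitory receptors, so their medians are not separate results. Age-associated-like cells made up 18.9% and 13.8% of cells, so both medians also carry their share. Within that class the medians were 0.19 for the age-associated program and 0.39 for inhibitory receptors. NK receptor genes had a median of 0.57 (percentile 100), with 11 of 15 higher, such as Fcer1g (3.10) and Klrb1c (2.99), and 3 lower, such as Klra3 (-1.37). Fcer1g, Klrb1c and Klrk1 were among the genes leading the NK-like cluster (3.89% and 1.29% of cells), so this median also carries its share. Transcription factors tied to exhaustion had a median of 0.30 [0.21, 0.40] (percentile 100), with 9 of 14 higher, including Ikzf2 (2.41 [2.18, 2.65]), Irf4 (0.91) and Maf (0.85). Ikzf2 was also among the genes leading the NK-like cluster and unnamed cluster 9, which has markers of regulatory T cells, so its ratio carries the shares of these cells. Of 9 tissue residency genes, 5 were higher and 1 lower, with a median of 0.39 [0.28, 0.50] and with Itgae at 1.48 [1.34, 1.62] and the gut-homing receptor gene Ccr9 at 2.02 [1.84, 2.21]. Itgae and Ccr9 were among the genes leading naive-like cluster 0 (25.8% and 8.63% of cells), so their ratios also carry its share. Of 13 MHC class I genes, 12 were higher, with a median of 0.22 [0.19, 0.24] (percentile 100), as for H2-Q6 (0.51) and H2-Q7 (0.44).

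General memory genes went the other way. Of 15, only 1 was higher in the recipient and 13 were lower, with Ly6c2, Ifitm10, Il18r1 and Il2rb among them, and the median was -0.48 [-0.51, -0.43] (percentile 0). Ly6c2 had 2141 CPM in unnamed cluster 2 (4.96% and 20.6% of cells) and 229 in naive-like cluster 0 (25.8% and 8.63%). The ratios of memory genes therefore also carry the make-up of the cells. Cytotoxic granule genes had 4 members higher, led by Gzma, and 6 lower, led by Gzmm, with a median of -0.15 [-0.20, -0.03]. Naive and stem-like genes were mixed, with 7 of 15 higher and 6 lower, from Igfbp4 to Dapl1 (-0.28), and a median of 0.07 [-0.01, 0.12]. Chemokine and cytokine genes had a median of 0.27 [0.19, 0.62], with 5 of 10 higher, such as Ccl3 (1.35 [1.22, 1.47]), and Xcl1 lower (-0.48). Homing receptor genes had 7 of 14 higher, such as Cxcr4 (1.68), and 5 lower, such as Ccr2 (-0.79), with a median of 0.14 [0.10, 0.19].

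The remaining lists had small medians. Interferon response genes stood at 0.13 [0.10, 0.20], with 10 of 17 higher, such as Ifi27l2a (0.59) and Isg20 (0.43). Immediate early genes stood at 0.12 [0.10, 0.17], with 9 of 14 higher, such as Egr1 (0.81) and Fos (0.42). Autophagy and lysosome genes stood at 0.12 [0.07, 0.15] (percentile 98.8), with 6 of 12 higher, such as Ctsl. Senescence genes stood at 0.16 [0.06, 0.25] (percentile 93.9), with 3 of 9 higher, such as Gadd45b, and 6 with intervals holding 0. Glycolysis genes, with 8 of 14 higher, such as Pkm, stood at 0.07 [0.04, 0.08], near what random lists gave (percentile 82.1). Cell cycle genes (0.08 [0.01, 0.15]), oxidative phosphorylation genes (0.01 [0.00, 0.03]) and heat shock genes (-0.02 [-0.06, 0.00]) were close to 0, with Hsp90ab1 at -0.12 [-0.13, -0.10].

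Among cells with at least 3500 UMIs, each thinned to 3500, Gzmk was found in 19.0% (17.9 to 20.2) of recipient and 14.0% (13.2 to 14.9) of donor cells. The share in naive-like cells was 0.534% and 0.256%, at median depths of 7501 and 7871.5 UMIs in the naive-like cells. Thinning left out 489 recipient and 463 donor cells as too shallow. This removed 20.3% and 21.7% of age-associated-like cells but 2.65% and 1.26% of naive-like cells. Effector-memory-like cells had median depths of 3347 and 3386 UMIs, so most of them were left out. The thinned shares therefore do not cover all classes alike. Without thinning, Gzmk was found in 23.4% and 18.4% of all cells. Pdcd1 was found in 5.28% (4.66 to 5.94) of recipient and 3.33% (2.93 to 3.78) of donor cells, with 0.534% and 0% (limit 0.256%) in naive-like cells and 7.81% and 5.45% of all cells without thinning. The shares with Lag3 (6.29% and 3.53%), Tox (17.6% and 13.5%), Tigit (10.3% and 7.46%), Klrg1 (4.31% and 2.23%) Gzmb (5.13% and 3.05%) and Gzma (1.94% and 0.873%) were higher in the recipient too. In naive-like cells these were 0.534% and 0.597% for Lag3, 10.2% and 8.27% for Tox, 0.214% and 0.171% for Tigit, 0.0534% and 0% (limit 0.256%) for Klrg1, 0.534% and 0.0853% for Gzmb, and 0.214% and 0% (limit 0.256%) for Gzma. Without thinning they were 9.74% and 5.89% for Lag3, 29.0% and 23.2% for Tox, 13.7% and 11.5% for Tigit, 6.52% and 3.84% for Klrg1, 8.65% and 5.46% for Gzmb, and 3.65% and 1.91% for Gzma. Within the recipient, Pdcd1 was found in 22.7% (20.1 to 25.6) of cells with Gzmk and 1.17% of cells without, and within the donor in 19.8% (17.3 to 22.4) and 0.649%.

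Ly6c2 was found in 46.1% (44.7 to 47.5) of recipient and 73.1% (72.0 to 74.1) of donor cells, with 25.0% and 41.4% in naive-like cells and 50.7% and 73.4% without thinning. Cxcr3 was found in 27.5% (26.2 to 28.7) and 41.2% (40.1 to 42.4), with 4.17% and 12.8% in naive-like cells and 40.5% and 63.0% without thinning. Ccl5 was found in 56.3% (54.9 to 57.7) of recipient and 74.5% (73.5 to 75.5) of donor cells, although its CPM was nearly the same, with 20.6% and 19.9% in naive-like cells and 66.7% and 79.4% without thinning. Il7r (56.4% and 65.9%), Eomes (20.3% and 24.3%) and Cd44 (12.2% and 15.4%) also had lower shares in the recipient, with 56.4% and 63.3%, 3.26% and 3.75%, and 2.62% and 3.07% in naive-like cells. Without thinning Il7r was found in 68.9% and 80.5%, Eomes in 30.4% and 40.8%, and Cd44 in 19.8% and 29.7% of cells. Ccr7 was found in 53.5% (52.0 to 54.9) and 48.4% (47.2 to 49.6), but in 64.6% and 66.0% without thinning, so its order hung on depth, and in naive-like cells it was found in 78.4% and 78.1%.

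**Figure D2:**
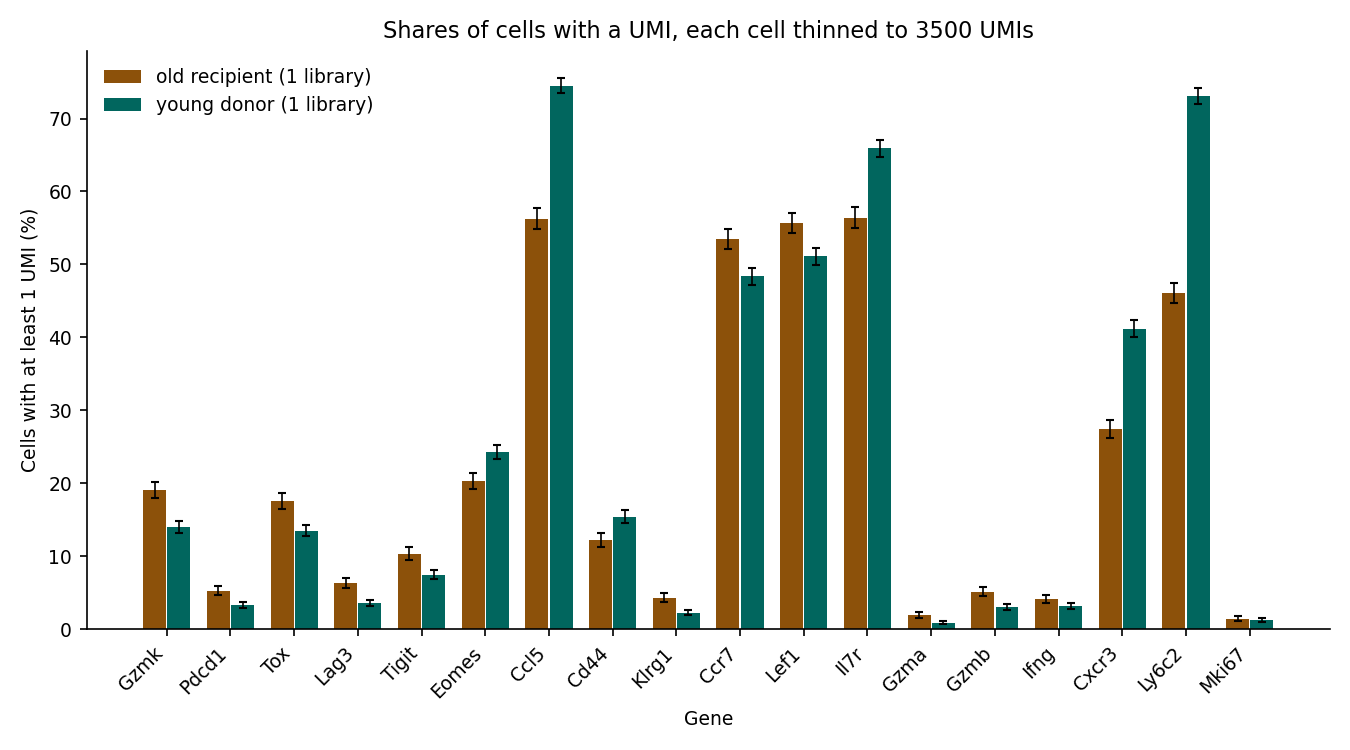
Shares of cells with at least 1 UMI of each gene, among cells with at least 3500 UMIs, each thinned to 3500, in 1 library per group. Bars are exact binomial 95% intervals.

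Naive-like cells made up 36.0% (34.7 to 37.3) of recipient and 15.9% (15.1 to 16.8) of donor cells, and age-associated-like cells, marked by Gzmk, Pdcd1 and Tox, 18.9% (17.9 to 20.01) and 13.8% (13.0 to 14.6). Pdcd1 was not particular to this class, at 69.5 CPM in unnamed cluster 8 and 63.0 in cluster 1, the larger age-associated-like cluster. Gzmk stood at 231 CPM in cluster 8 and 1160 in cluster 1, and Tox at 87.8 and 231. Central-memory-like cells made up 3.39% and 10.1%, effector-memory-like cells 3.52% and 1.62%, interferon-stimulated-like cells 7.56% and 7.26%, NK-like cells 3.89% and 1.29%, cycling-like cells 1.22% and 1.41%, and immediate-early-like cells 1.40% and 0.966%. The central-memory-like share hung on naming and grouping, at 14.7% and 44.0% with looser naming, chosen after the data were seen, and 11.5% and 25.4% with genes centred within each library. Interferon-stimulated-like cells were 1.14% and 1.72% at resolution 0.6, and NK-like cells 3.48% and 0.362% with genes centred. Unnamed clusters held 24.1% and 47.7%, of which cluster 2 held 4.96% and 20.6%, cluster 3 held 8.29% and 11.96%, cluster 6 held 2.38% and 9.45%, cluster 8 held 3.99% and 3.81%, and cluster 9 held 4.47% and 1.80%. Of the naive-like clusters, cluster 0 held 25.8% of recipient and 8.63% of donor cells, and cluster 5 held 7.86% and 6.21%. No direction was read from the class shares, because genes leading these clusters, such as Igfbp4, Ccr9 and Fcgrt, differed between the libraries. With each library clustered alone, naive-like cells were 21.5% and 30.8% and age-associated-like cells 19.6% and 19.9%.

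**Figure D3:**
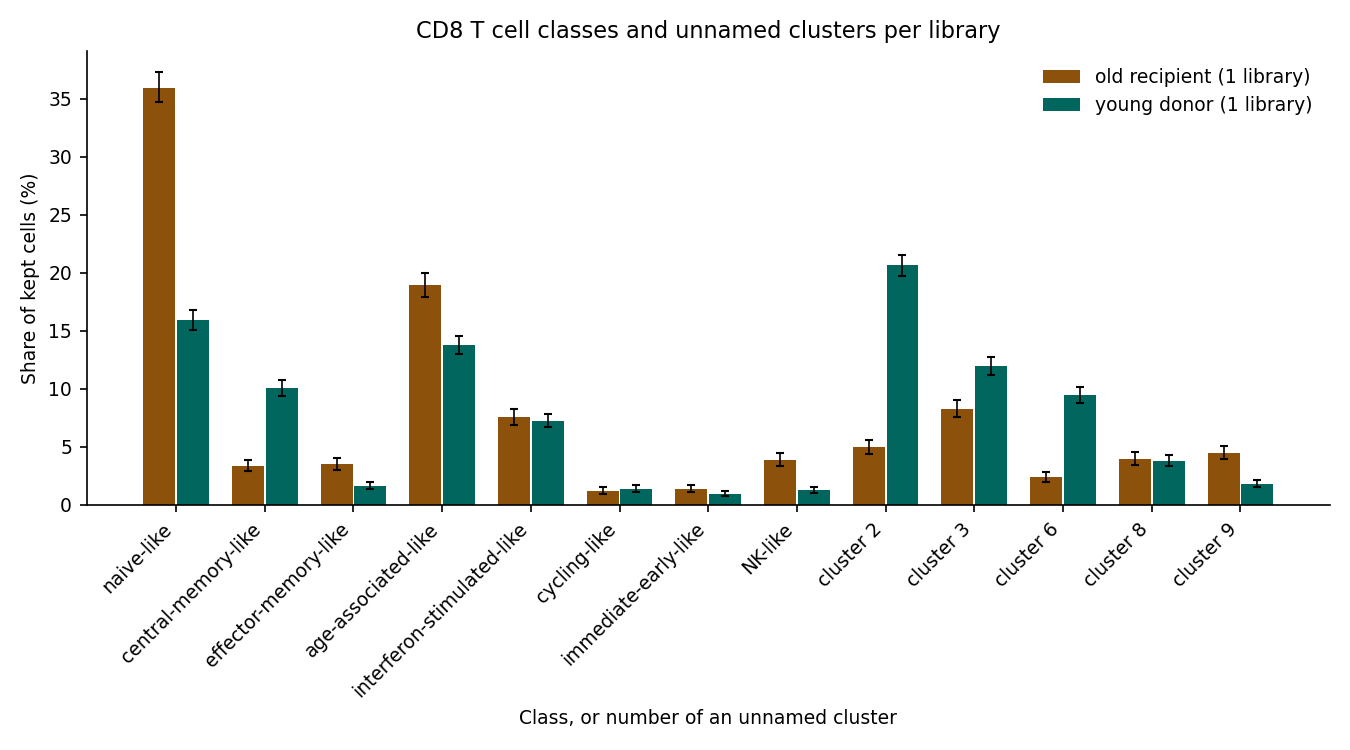
Shares of kept cells in each named class and each unnamed cluster, in 1 library per group. Bars are exact binomial 95% intervals.

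Within age-associated-like cells (1011 recipient and 1026 donor cells), Penk (chromosome 4, 4133531 to 4138819), the proenkephalin gene, had 68.7 CPM in the recipient and 6.52 in the donor, a log2 ratio of 3.40 [2.86, 3.98]. Ikzf2, which encodes Helios, had 57.2 and 17.5 CPM (1.71 [1.35, 2.08]), and the chemokine genes Ccl4 and Ccl3 had ratios of 1.31 [1.22, 1.40] and 1.18 [1.04, 1.33]. Cd72 (1.08) and Btg2 (0.99) were higher as well. Klra1 (chromosome 6, 130363917 to 130386874), the Ly49A gene, had 0 UMIs in the recipient and 379 in the donor, at least 128-fold higher in the donor. Ctse (-1.89 [-2.16, -1.63]), Ccr2 (-0.94 [-1.12, -0.76]), Gzma (-0.80 [-1.09, -0.51]), Hspa9 (-0.53) and Klrc1 (-0.48) were lower in the recipient.

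Gzmk itself, which helped to set this class apart, stood at 1259.8 and 1114 CPM, a ratio of 0.18 [0.12, 0.23], and was found in 94.5% and 92.8% of cells after thinning. Of 14 genes of the age-associated program, 8 were higher in the recipient and none lower, with a median of 0.19 [0.12, 0.24] (percentile 100). Pdcd1, Lag3, Tigit, Ctla4 and Cd160 were in this list and in that of inhibitory receptors. Of 9 inhibitory receptor genes, 5 were higher, with Lag3 at 0.72 [0.55, 0.88], Ctla4 at 0.68 [0.36, 0.99], Pdcd1 at 0.39 [0.19, 0.58] and Tigit at 0.35 [0.23, 0.47], and the median was 0.39 [0.29, 0.56] (percentile 100). The intervals of Tox (-0.09 [-0.21, 0.03]), Eomes (0.03 [-0.08, 0.14]) and Cd44 (-0.10 [-0.32, 0.12]) held 0. Chemokine and cytokine genes (0.19 [0.08, 0.42]), exhaustion transcription factors (0.15 [0.03, 0.25]) and MHC class I genes (0.07 [0.04, 0.12]) had positive medians, and NK receptor genes a negative one (-0.23 [-0.48, -0.02]). Ccl3, Ccl4, Lag3, Pdcd1 and Penk led the smaller of the 2 clusters in this class, and Gzmk, Tigit, Tox and Klrg1 the larger. The smaller held nearly like parts of the class, 82 of 1011 recipient and 77 of 1026 donor cells. Its recipient cells were deeper, at medians of 3832.5 and 3032 UMIs. The ratios may therefore carry both this mix and levels within the smaller cluster. In the larger cluster alone, an alternative chosen after the data were seen, Penk stayed at 2.58 [2.02, 3.18], Ccl4 stood at 0.47 [0.36, 0.58], Ccl3 at 0.22 [0.03, 0.42] and Gzma at 1.06. Without the 3 most common Trbv segments of either library, also chosen then, NK receptor genes turned to 0.50 [0.31, 0.72], Pdcd1 stood at -0.19 [-0.47, 0.09] and Klrc1 at 0.22 [-0.09, 0.54], and the median of inhibitory receptor genes had an interval holding 0. Ly6c2 in this class stood at 0.43 but at -1.65 with each library clustered alone. With at most 5% mitochondrial UMIs, where the class was 3.39% and 1.92% of cells, Ikzf2 stood at 2.96, Ccr2 at -1.74, Gzma at -4.01 and chemokine and cytokine genes at 0.89.

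Receptor beta segments in age-associated-like cells differed between the libraries. In the recipient the leading segments were Trbv16 in 16.1% (13.8 to 18.5), Trbv13-2 in 11.8% and Trbv5 in 9.68% of cells with a segment, whereas the donor had 0.197% with Trbv16 and 0 of 1014 with Trbv5 (limit 0.296%). The donor was led by Trbv12-1 in 22.6% (20.04 to 25.3), Trbv17 in 22.4% and Trbv19 in 14.8%. With equal numbers of cells, the inverse Simpson index was 12.1 in the recipient and 6.89 in the donor, against 17.4 and 17.1 in naive-like cells. The overlap of segment shares between the libraries was 39.3% in age-associated-like, 25.7% in effector-memory-like and 90.9% in naive-like cells. In effector-memory-like cells, Trbv29 was found in 52.5% (44.9 to 60.1) of recipient and none of the donor cells, and Trbv31 in 33.6% of donor and 1.69% of recipient cells. Several genes followed these segments, with shares taken over cells with an assigned segment. Of donor Klra1 UMIs, 98.9% were in Trbv12-1 cells, and recipient Trbv5 cells held 47.3% of the Ccl3 UMIs and 41.9% of the Penk UMIs. Donor Trbv14 cells (5.82%) held 58.8% of the Gzma UMIs, and recipient Trbv29 cells 66.3% of those in effector-memory-like cells. Trbv12-1 and Trbv12-2 are nearly identical, as are the Trbv13 segments, so reads may be shared between them.

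**Figure D4:**
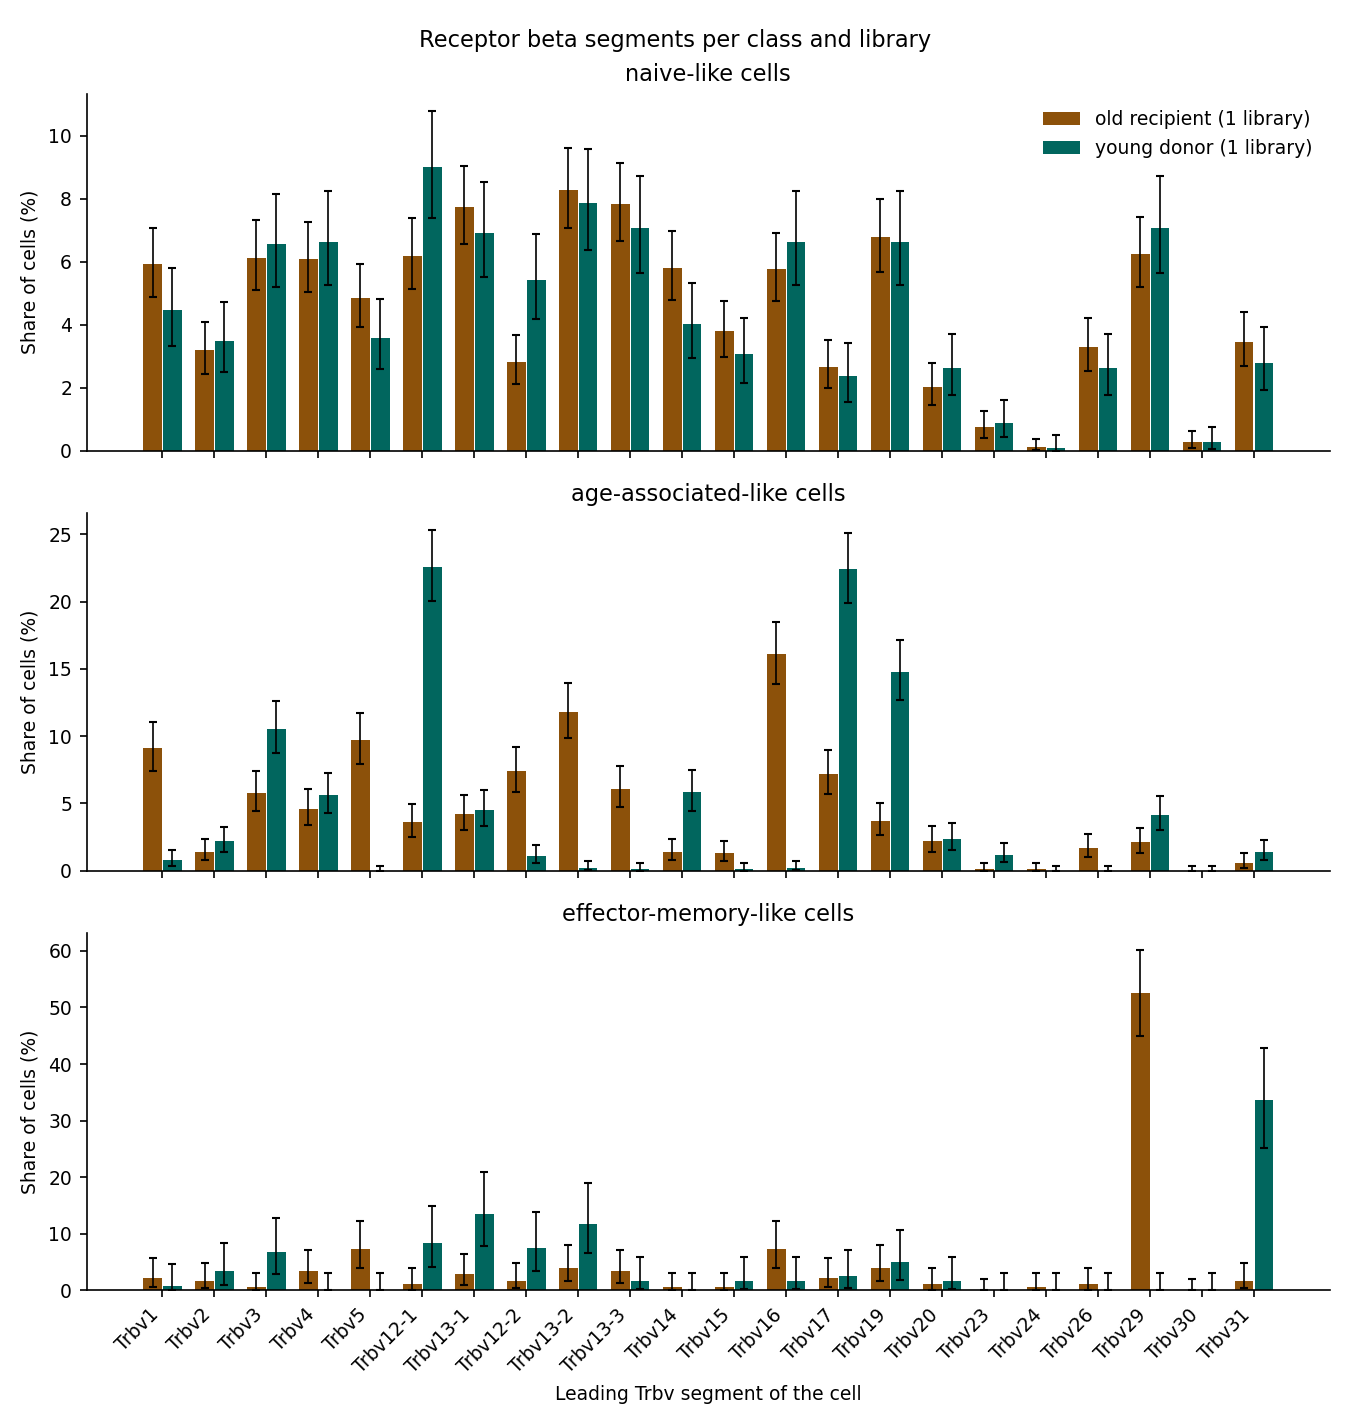
Shares of cells by leading Trbv segment in naive-like, age-associated-like and effector-memory-like cells, in 1 library per group. Bars are exact binomial 95% intervals.

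Within naive-like cells (1922 recipient and 1188 donor cells), Ctse had 15.7 and 94.9 CPM, 6.05-fold higher in the donor, with a log2 ratio of -2.60 [-2.81, -2.39]. Il18r1 (-0.91 [-1.11, -0.72]), Ahnak (-0.88), Cd55 (-0.85), Ly6c2 (-0.83 [-0.90, -0.76]) and Nme4 (-0.70) were lower in the recipient. Btg2 (1.13 [0.97, 1.28]), Ccr9 (0.86 [0.66, 1.07]), Sgk1 (0.63), Ramp1 (0.60), Ddit4 (0.51) and Id2 (0.50) were higher. General memory genes had a median of -0.39 [-0.68, -0.27] (percentile 0), with 10 of 15 lower, such as Cxcr3 (-1.50 [-1.74, -1.27]) and Ifitm10 (-1.12). Ccl5 was lower (-0.66 [-0.73, -0.58]) and so were Tnf (-0.39) and Tnfsf8 (-0.28), with a chemokine and cytokine median of -0.39 [-0.63, -0.10]. The share of these cells with Ccl5 was not lower in the recipient, at 20.6% and 19.9% after thinning and 34.5% and 28.4% without. Naive and stem-like genes had a median of 0.02 [-0.03, 0.05], although Igfbp4 (0.31) was higher and Dapl1 (-0.59) lower. Genes of the age-associated program had a median of 0.22 [0.09, 0.47], with Tox at 0.38 [0.15, 0.61], and tissue residency genes one of 0.32 [0.06, 0.49]. Ccr9, Ramp1, Igfbp4 and Itgae were among the genes leading cluster 0, which held 1376 of 1922 recipient and 643 of 1188 donor naive-like cells, so their ratios also carry that mix. The lower Ccl5 and Ly6c2 carry it too, since Ccl5 had 129 CPM in cluster 0 and 467 in cluster 5, and Ly6c2 229 and 532. Values hung on how cells were grouped. With each library clustered alone, Ly6c2 stood at -1.67, Ccl5 at -1.34, Cxcr3 at -2.33, Ifitm10 at -1.85 and Cd55 at -0.23. At resolution 0.6 Ccl5 stood at -0.06.

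Within central-memory-like cells (181 and 751 cells), Btg2 (1.14), Anxa2 (0.83), Cst3 (0.76), Trnau1ap (0.62), Pqbp1 (0.61) and Erp44 (0.58) were higher in the recipient. Ctse (-2.47 [-3.24, -1.79]), Fcgrt (-1.27 [-1.61, -0.94]), Gzmm (-1.17 [-1.50, -0.85]), Dapl1 (-1.13 [-1.35, -0.92]), Prkag1 (-0.77) and Mgst2 (-0.67) were lower. General memory genes showed no shift as a list here (-0.04 [-0.09, 0.02]), with 12 of 15 intervals holding 0. B cell genes had a median of 3.12 [2.59, 3.96] over 4 measured genes in this class, which stood at 0.31 with genes centred within each library and at 0.07 at resolution 1.5. With genes centred, Gzmm stood at -1.86, Dapl1 at -0.31, Anxa2 at 0.23, Cst3 at 0.13 and Mgst2 at -0.06.

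Within effector-memory-like cells (188 and 121 cells), Gzma had 2441 CPM in the recipient and 307 in the donor, 7.96-fold, a log2 ratio of 2.99 [2.74, 3.25]. Ly6a (1.39), Cxcr6 (1.36), Itgb1 (1.34 [1.07, 1.63]), Baiap3 (1.23) and Ddit4 (1.19) were higher, and effector memory genes had a median of 0.33 [0.20, 0.46] (percentile 100), with 9 of 14 higher. Gzmm (-1.22 [-1.76, -0.70]), Ier3 (-1.09), Tox (-1.08), Il7r (-0.92 [-1.20, -0.64]), Tcp1 (-0.82), Wdr95 (-0.82) and Eomes (-0.78 [-1.34, -0.23]) were lower. The interval of Gzmk (-0.14 [-0.43, 0.14]) held 0. The 14 Trbv13-2 cells, 11.8% of the donor's cells with a segment here, held 57.7% of the Gzmm UMIs in such cells.

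Within interferon-stimulated-like cells (404 and 541 cells), Btg2 (1.13), Gzmk (0.74 [0.46, 1.01]), Ramp1 (0.56), Igfbp4 (0.53), Lars2 (0.51) and Sp140 (0.50) were higher in the recipient. Ctse (-2.17), Fcgrt (-1.65 [-2.07, -1.25]), S100a6 (-1.26 [-1.44, -1.08]), Itgb1 (-0.96), Cxcr3 (-0.90 [-1.13, -0.67]) and Lgals1 (-0.72) were lower. Interferon response genes did not differ as a list (-0.03 [-0.07, 0.07]), with 14 of 17 intervals holding 0, whereas 12 of 15 general memory genes were lower (-0.52 [-0.67, -0.35], percentile 0). The class joins cluster 7, where Ccl5 had 292 CPM, and cluster 13, where it had 11116, and cluster 13 held 61 of the 404 recipient and 140 of the 541 donor cells, so the memory gene ratios also carry this mix. With genes centred within each library, Ramp1 stood at 1.92 and Igfbp4 at 1.503.

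Genes of other cell types were rare in both libraries. Those of CD4 and regulatory T cells had a median of 1.52 [1.14, 1.99], with all 7 measured genes higher in the recipient, such as Izumo1r (2.05 [1.87, 2.23]), at 25.1 and 6.08 CPM. Izumo1r, Ctla4 and Ikzf2 were among the genes leading unnamed cluster 9 (4.47% and 1.80% of cells), which had Cd8a at 525 and Cd8b1 at 1331 CPM but Cd4 at 0.751. NK cell genes had a median of 0.79 [0.49, 1.40], with 5 of 7 higher, and stood at 1.54 when genes with 1 UMI were counted and at 2.29 with genes of at least 100 UMIs only. B cell genes had a median of 0.44 [0.39, 0.50], with Cd74 at 1.33 and Igkc at 0.67. Gamma delta T cell genes had a median of 0.73 [0.43, 0.85], but Cd163l1, with 5 UMIs in the recipient and 657 in the donor, stood apart. Myeloid genes (-0.14 [-0.24, 0.12]), granulocyte genes (0.07 [-0.26, 0.43]) and erythroid genes (-0.16 [-0.38, 0.07]) had intervals holding 0, and too few plasma cell and platelet genes were measured for a median. Xist was high in both libraries, at 345 and 402 CPM, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 UMIs in both, below limits of 0.0788 and 0.0515 CPM.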

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

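None of these differences was tested, and every check of an explanation below was chosen only after the result was seen. Several genes had ratios of opposite sign in different classes. Ccl5 stood at 0.16 in effector-memory-like and -0.66 in naive-like cells, Tcf7 at 0.25 in central-memory-like and -0.15 in age-associated-like cells, and Gzma at 2.99 in effector-memory-like and -0.80 in age-associated-like cells. The naive-like value of Ccl5 ranged from -0.06 at resolution 0.6, with an interval holding 0, to -1.49 with genes centred within each library. Gzma in age-associated-like cells turned to 1.32 with genes centred, so the contrasts of these 2 genes hung on grouping. Some lists also had medians of opposite sign in different classes. General memory genes had medians of 0.15 in effector-memory-like and -0.52 in interferon-stimulated-like cells, effector memory genes 0.33 in effector-memory-like and -0.13 in naive-like cells, and chemokine and cytokine genes 0.19 in age-associated-like and -0.39 in naive-like cells. Homing receptor genes had 0.19 in effector-memory-like and -0.14 in central-memory-like cells, NK receptor genes 0.64 in central-memory-like and -0.23 in age-associated-like cells, and tissue residency genes 0.32 in naive-like and -0.45 in central-memory-like cells. The contrast of NK receptor genes turned, with -0.36 in central-memory-like cells with genes centred, and 1.97 in age-associated-like cells with at most 5% mitochondrial UMIs. Gzmk had 84.0 CPM (64.3 to 108) in the recipient and 38.2 (24.7 to 56.4) in the donor barcodes left out for few genes or high mitochondrial shares, against 189 and 112 in kept cells.

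The donor library held age-associated-like cells 1 month after transfer, and 14.0% of donor cells with at least 3500 UMIs had a Gzmk UMI after thinning. They could be host cells sorted by mistake, but the recipient's 3 leading segments Trbv16, Trbv13-2 and Trbv5 were found in 0.394% of donor cells of this class, against 37.5% in the recipient. That speaks only against cells of the mouse behind the recipient library, and host cells of another mouse stay open. They could be free Gzmk RNA, but only 0.256% of donor naive-like cells had a Gzmk UMI after thinning. They could also have been among the transferred cells, which stays open, because 0 libraries of cells before transfer were held.

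Ctse was lower in the recipient in all 5 classes, with the smallest distance, -1.83, in effector-memory-like cells, so it may reflect the strain and not age. The CD45.1 mice carry another allele of Ptprc (chromosome 1, 138062861 to 138175708) with neighbouring chromosome. Of 5 genes alike in all 5 classes, 3 (60%, interval 14.7 to 94.7) lay within 20 Mb of Ptprc, against 1.27% of 5659 genes, namely Ctse, Btg2 and Rnpep (chromosome 1, 135262712 to 135284084), as linked variants would need, although Ctse itself prompted the question and is counted among the 3. The test was first run with at least 100 UMIs in each class, where 1 of 1 gene lay there, and then with at least 20. Apobec2 (-1.30) and Gm10073 (-0.67) lay elsewhere and are not accounted for.

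Ccl5 was found in 74.5% of donor but fewer recipient cells after thinning to equal depth, at nearly equal CPM, so free RNA could have spread it. Earlier checks that used naive-like cells were replaced, after their results were seen, by one that uses no names. At least 10 UMIs of Ccl5 were found in 60.3% (59.1 to 61.45) of donor and 38.7% of recipient cells, and free RNA, at the highest rate the donor cells without Ccl5 allow, could bring the recipient to 41.15% at most if it reached all cells alike. A second reading is that names of classes moved, since the naive-like ratio was 2.26 with both libraries together and 0.699 with each alone, but the Ccl5 shares do not rest on names.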

How the results depend on the processing

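Of 18 alternatives, 15 were planned and 3 were chosen only after the data were seen. In all, 793 values were followed, 14 of them leading. Of 409 signed values with an interval beyond 0, 46 changed sign at least once. No paired analysis was possible because there was 1 library per group and the labels do not pair them, and leaving out a library was not possible either. For every value below the cause was not tested. Values are recipient over donor, log2 for genes and lists and plain ratios for class shares, and the value with the settings of the report follows in parentheses.

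With each library clustered alone, the naive-like share ratio was 0.699 (from 2.26) and the age-associated-like one 0.984 (from 1.37). In age-associated-like cells the sign changed with an interval beyond 0 for Foxp1 at -0.26 (from 0.25), Lef1 at -0.38 (from 0.24), Ly6c2 at -1.65 (from 0.43), naive and stem-like genes at -0.41 (from 0.12) and tissue residency genes at -0.30 (from 0.13). It changed with an interval holding 0 for Ahnak at 0.051 (from -0.18), Fos at -0.21 (from 0.52), Klrk1 at 0.0092 (from -0.23), NK receptor genes at 0.0097 (from -0.23) and CD4 and regulatory T cell genes at -0.33 (from 0.46). The age-associated program moved to 0.37 (from 0.19). In naive-like cells the sign changed with an interval beyond 0 for Ighm at -0.10 (from 0.15), Il7r at 0.25 (from -0.305), Itga4 at 0.55 (from -0.19), Rtp4 at -0.22 (from 0.44) and Uqcrq at -0.10 (from 0.09). It changed with an interval holding 0 for Atp5e at -0.032 (from 0.09), Cd69 at 0.082 (from -0.16), Itga6 at 0.035 (from -0.35), Klf6 at 0.090 (from -0.45), Srgn at 0.019 (from -0.07) and glycolysis genes at -0.0067 (from 0.09). Naive and stem-like genes moved to 0.23 (from 0.02).

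With genes centred within each library, the ratio of central-memory-like shares was 0.453 (from 0.336) and of naive-like shares 1.68 (from 2.26). In central-memory-like cells the sign changed with an interval beyond 0 for Ifi27l2a at 0.64 (from -0.46), Ly6a at 0.31 (from -0.48), NK receptor genes at -0.36 (from 0.64) and Vim at -0.18 (from 0.13). In age-associated-like cells the same held for Gzma at 1.32 (from -0.80), and the age-associated program moved to 0.31 (from 0.19). Signs changed with an interval holding 0 for Cox4i1 at 0.014 (from -0.10) and Klra3 at -0.18 (from 0.99) in central-memory-like cells and for Itga4 at 0.020 (from -0.19) in naive-like cells. In interferon-stimulated-like cells this held for Klrd1 at -0.16 (from 0.21) and S100a4 at -0.29 (from 0.98).

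With at most 5% mitochondrial UMIs, age-associated-like cells were 3.39% and 1.92%, a ratio of 1.76 (from 1.37), and the effector-memory-like ratio was 2.93 (from 2.17). Within age-associated-like cells the sign changed with an interval beyond 0 for Klrc1 at 1.28 (from -0.48), Klrk1 at 2.91 (from -0.23), NK receptor genes at 1.97 (from -0.23), S100a4 at -1.42 (from 0.64) and Zeb2 at 2.91 (from -0.51). It changed with an interval holding 0 for Gzmb at -0.13 (from 0.24), H2-Q6 at -0.083 (from 0.28), Ly6c2 at -0.37 (from 0.43), Mdm2 at -0.068 (from 0.31), Tcrg-C2 at -0.26 (from 0.64) and glycolysis genes at -0.065 (from 0.05). The inverse Simpson index of this class was 8.39 and 6.39 (from 12.1 and 6.89). With at least 1000 genes the index was 13.3 and 8.70, and Klrd1 stood at -0.078 (from 0.21) in interferon-stimulated-like cells, with an interval holding 0. With no doublets removed the index was 13.4 and 9.04, and Ly6c2 stood at -0.23 (from 0.43) in age-associated-like cells, with an interval beyond 0.

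At resolution 0.6 the age-associated-like ratio was 1.2504 and the naive-like one 2.44. With TMM scaling the general memory median over all cells was -0.53 (from -0.48). Gzmk was found in 23.4% and 18.4% of cells without thinning and in 15.5% and 11.3% after thinning to 1000 UMIs (from 19.0% and 14.0%).

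In the larger age-associated-like cluster alone, Gzma stood at 1.06 (from -0.80) with an interval beyond 0, and Ifng at -0.17 (from 0.23) and Rgs1 at -0.015 (from 0.21) with intervals holding 0. Without the 3 most common Trbv segments, the sign changed in age-associated-like cells with an interval beyond 0 for Klrk1 at 1.07, NK receptor genes at 0.50, Tcrg-C2 at -0.65 (from 0.64) and Tcrg-C4 at -0.60 (from 0.82). It changed with an interval holding 0 for Gzmb at -0.10, Ifng at -0.0040, Klrc1 at 0.22, Pdcd1 at -0.19 (from 0.39) and exhaustion transcription factors at -0.0028 (from 0.15). In central-memory-like cells Gzmb stood at -0.23 (from 1.72) and Ifi27l2a at 0.042 (from -0.46), with intervals holding 0.

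The central-memory-like ratio gave no value with 1000 variable genes, resolution 0.6, at least 1000 genes, at most 5% mitochondrial UMIs or no doublets removed. It gave none with each library clustered alone either, where the recipient had 14.3% and the donor 0%. Interferon-stimulated-like cells were 2.52% and 2.48% with at least 1000 genes, 1.19% and 1.80% with no doublets removed, 2.32% and 2.43% with genes centred, and 1.14% and 2.17% with each library clustered alone. NK-like cells were then 4.01% and 0%.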

Other observations

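Every check named here was chosen only after the results were seen. Over all cells, old recipient cells carried more Gzma, Gzmb, Klrg1 and Cx3cr1 than young donor cells, with Cx3cr1 at 17.3 and 8.14 CPM. These genes lead the effector-memory-like cluster, which held 3.52% and 1.62% of cells, and Gzma stood at -0.80 within age-associated-like cells, so these values do not separate the make-up of the cells from levels within them. Ikzf2 had 18.0 and 3.38 CPM over all cells, and its higher level was seen again within age-associated-like cells. Part of that followed 1 segment. Recipient Trbv5 cells, 9.68% of the cells with a segment in this class, held 24.6% of their Ikzf2 UMIs. Both Ccr9 and Itgae, tied to gut homing and to tissue retention, were higher in the recipient over all cells and within naive-like cells. Itgae stood there at 0.43 [0.26, 0.60], and at 1.22 with each library clustered alone, and both genes lead a cluster that held unequal parts of the naive-like cells.

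A hypothesis is that Gzmk-expressing cells in both populations grew in part from large clones, since segments were uneven and overlapped by 39.3% between the libraries, against 90.9% in naive-like cells. The recipient's 3 leading segments were found in 0.394% of the donor's age-associated-like cells, which separate growth of those clones could give. However, Trbv3, Trbv4 and Trbv17 were common in both libraries. Among cells of this class with both a Trbv and a Trav segment, Trbv3 with Trav7-6 was in 46 of 514 donor and 0 of 776 recipient cells. Trbv4 with Trav7-6 was in 45 donor and 0 recipient cells. Trbv17 was not among the leading pairs, so its sharing stays open. Neither were Trbv12-1, which led the donor and held 98.9% of its Klra1 UMIs, and Trbv16, which led the recipient. Klra1 and part of the Pdcd1 ratio may then mark clones and not age, but the pairs tie neither gene to a single clone. Without the 3 most common segments of either library, Pdcd1 no longer stood higher in the recipient's age-associated-like cells. It stood at -0.19 [-0.47, 0.09], an interval that holds 0. Several segments were left out at once, so this value points to no single clone. Penk and Ccl3 stayed higher in the recipient without those segments, but clones with other segments were left in, so whether clones account for them stays open.

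Another hypothesis is that donor cells in the aged host took on memory traits, with more Ly6c2, Il2rb and Cxcr3. The general memory median lay below 0 within naive-like and interferon-stimulated-like cells. Its interval held 0 within central-memory-like and age-associated-like cells, and it stood at 0.15 [0.003, 0.24] within effector-memory-like cells. The medians below 0 do not separate levels from the mix of clusters in a class. Cluster 13, high in Ccl5, held 61 of 404 recipient and 140 of 541 donor interferon-stimulated-like cells. Cluster 0, low in Ly6c2 and Ccl5, held 1376 of 1922 recipient and 643 of 1188 donor naive-like cells. The Ccl5 share of 74.5% in the donor goes with this hypothesis, although the CPM of Ccl5 was nearly equal. Growth after transfer into the host could give the same picture. Memory-like cells could also have been among the transferred cells, and 0 libraries from before transfer were held to check this. Receptor sequences of the same cells and donor cells placed in young hosts would help to tell these readings apart.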
